A study of Homo sapiens with 4 samples.

How the data were processed

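Total RNA of HT-29 cells was sequenced from 2 untreated and 2 Gemini-Cur cultures (48 h); per the labels' protocols it was extracted with TRIzol, treated with DNase I and made into libraries by random fragmentation of cDNA and adaptor ligation. The deposited files give read counts, 1 file per library for genes and 1 for lncRNAs, each ending with the 5 summary lines of HTSeq. Per the submitters' processing notes the tools were Trimmomatic 0.39, FastQC, HISAT2 and HTSeq, with genome build GRCh38; the annotation, the strand setting and how ribosomal RNA was handled are not given in the sources used here. The deposited counts are whole numbers and were not normalized. Each gene file held 70711 gene lines and each lncRNA file 20827, all of which also occur in the gene file. Libraries were grouped by their titles. Of the gene identifiers, 62666 were found in a table of gene names and 58228 in GENCODE 29 on GRCh38, which gave symbols, positions, exon lengths and GC content; this release is not stated to be the authors' annotation.

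The summary lines stayed out of library sizes and tests. Reads assigned to no gene were 6.58%, 5.63%, 28.2% and 6.49% of uniquely aligned reads in untreated replicates 1 and 2 and Gemini-Cur replicates 1 and 2, reads overlapping several genes 19.4%, 21.96%, 7.93% and 20.9%, and reads not aligned 26.6%, 21.1%, 12.5% and 18.1% of 88664962, 94796489, 88558012 and 74390856 reads. Wilson 95% intervals were at most 0.0152 points to either side. Reads were counted without molecular identifiers, so intervals cover counting error only. Because HTSeq leaves out reads that overlap several genes, overlapping, antisense and host genes are undercounted in the gene table, and the lncRNA table can include reads of overlapping genes. How it was counted is not given in the sources used here; no lncRNA had fewer reads there than in the gene table, as counting against lncRNAs alone would give. Reads aligned to several places were left out by HTSeq, which lowers counts of near-identical copies.

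Genes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit and test on the deposited counts, TMM factors, filterByExpr with a minimum count of 10 and a minimum total of 15), with Benjamini-Hochberg adjustment over 18612 genes and calls at an adjusted p under 0.05. For 5410 lncRNAs, library sizes and TMM factors came from the gene table, since a file of lncRNAs holds part of a library. CPM values use these effective library sizes. The SE of a log2 difference was derived as its absolute value over the square root of edgeR's F statistic. With so few libraries it cannot be read against a normal distribution. Values are given as mean ± SD over the 2 libraries of a group, or per library where the treated ones differ by more than 3-fold and for some other genes, a choice made after seeing the values. Log2 differences of single treated libraries are log2 CPM (prior count 2) minus the untreated mean. The biological coefficient of variation over the 4 libraries was 0.589. No 2 libraries agreed within sampling noise (chi-square per degree of freedom at least 54.3 for every pair).

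The 39 gene lists and the rule for named genes were set before the data were examined. Lists with at least 5 measured members were tested with camera of limma 3.58.1 on log2 CPM with an inter-gene correlation of 0.01, two-sided, adjusted over 36 lists. The estimated correlation comes from the same fit. With the estimated correlation, camera refers its statistic to the residual degrees of freedom, which are few with 4 libraries and fewer without a replicate. A list that does not pass there is therefore not shown to be unchanged. Beside the camera test stands the edgeR p of each member adjusted over the list alone. Of 918 listed symbols 917 were found. Genes were named as follows. With no gene called, the 5 smallest unadjusted p in each direction were taken, with a mean of at least 5 CPM, a symbol, both treated libraries on the same side of both untreated ones, and no lncRNA, pseudogene, antisense or ribosomal RNA entry. For each list the 2 members with the smallest p were named, for lncRNAs the 5 smallest p in each direction with a mean of at least 1 CPM, and TP53, which the labels name. In the lncRNA list 4 are named, the last 2 of them chosen after their values were seen. Enrichment among called genes used Fisher's exact test against all 18612 genes tested, which takes genes as independent.

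Alternatives set before the data were examined were DESeq2's size factors, no filter or a stricter filter on low counts (1 CPM in 2 libraries), DESeq2 1.42.0 and limma-voom as tests, a threshold of 1.5-fold, the replicate number as a block, thinning to the smallest library (36908158 reads), leaving out mitochondrially encoded genes, lncRNA scaling from its own table, fry, an estimated correlation, and leaving out each replicate. Added after seeing the data were removal of exon length, GC content and genomic span trends (splines with 4 degrees of freedom, 17705 of 18612 genes matched), the estimated correlation together with that removal or without Gemini-Cur replicate 1, gene-table counts of lncRNAs, and the NRF2 list without AKR1C genes. Also after seeing the data, 12 lists were set against 10000 random lists each, matched on mean expression and exon length. Genes of the random lists were drawn independently of each other, whereas members of a list can vary together. A small share therefore does not tell an effect of the treatment from members that vary together in a single culture. Whether a list changed direction under an alternative was judged by the sign of its mean shift on the log2 CPM scale, in place of the direction camera gives, a choice also made after results had been seen.

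The scripts were tested on simulated counts for 18612 genes of which 200 were changed. With the spread of all 4 libraries, edgeR recovered 0% of 2-fold, 22% of 4-fold, 52% of 8-fold and 68% of 16-fold changes and called 0.0109% of unchanged genes. With the spread of the untreated libraries alone it recovered 56%, 66%, 70% and 80%. For 5410 lncRNAs it recovered 0%, 8%, 28% and 52%. In these simulated counts genes were drawn independently and no library stood apart, as Gemini-Cur replicate 1 does. The shares recovered and called therefore need not hold for these data. Camera recovered 4 of 4 shifted lists and called 0 of the other simulated lists. For this list test, genes were drawn independently of each other, with the spread of the untreated libraries alone. It therefore cannot tell how often the preset correlation gives false calls where genes of a list vary together or a treated library stands apart. Tables were read and figures drawn with Python 3.11.15, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.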

Results

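RNA abundance was measured by sequencing of total RNA from HT-29 cells, an established epithelial line from a human colorectal adenocarcinoma that carries mutant TP53. The cells were either left untreated or exposed for 48 h to Gemini-Cur, a nanoparticle form of curcumin, the yellow polyphenol of turmeric, at its IC50. The series held 4 libraries, 2 untreated and 2 treated with Gemini-Cur, and the comparison asked which transcripts differ in abundance after the treatment. Each library had a table of reads per gene and a table of reads per long non-coding RNA (lncRNA). Reads assigned to genes totalled 42154657 and 44108140 in untreated replicates 1 and 2, and 45326689 and 36908158 in Gemini-Cur replicates 1 and 2. A count above 0 was recorded for 23577, 20716, 26439 and 21238 genes in the same order. The lncRNA tables held 5094239 and 5174217 reads in the untreated libraries, and 2420399 and 3742444 in the treated ones. The untreated libraries are described as biological replicates and the treated ones only as replicates. The edgeR p-values of single genes thus measure the spread between these libraries, which can be partly technical. Camera p-values with a preset correlation set the genes of a list against the other genes tested. They do not measure whether a list would shift again in other cultures, also where a replicate is left out.

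Gemini-Cur replicate 1 stood apart from the other 3 libraries. Across 18612 genes, Pearson's r of log2 CPM (read counts scaled to library size) was 0.949 between the untreated libraries, 0.946 and 0.935 between Gemini-Cur replicate 2 and each of them, and 0.862 to 0.890 between Gemini-Cur replicate 1 and any other library. These correlations are across genes, which are not independent replicates. The first principal component, with 58.2% of the variance, separated Gemini-Cur replicate 1 from the rest. Mitochondrial ribosomal RNA took 33.3% of its gene counts, against 24.5% and 19.8% in the untreated libraries and 23.1% in Gemini-Cur replicate 2. RN7SL transcripts, the RNA part of the signal recognition particle and a family of near-identical copies, took 0.958%, against 5.43%, 8.55% and 5.70%. Reads overlapping several genes made up 7.93% of its uniquely aligned reads, against 19.4%, 21.96% and 20.9%. Wilson 95% intervals of these shares reached at most 0.0152 percentage points to either side and cover counting error only.

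**Figure D1:**
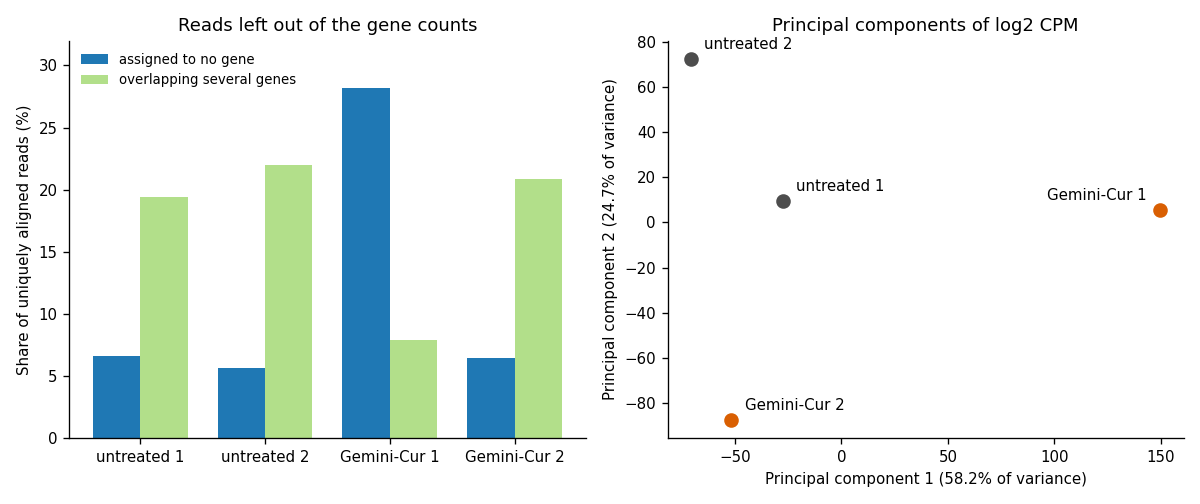
Left, share of uniquely aligned reads (percent) that were assigned to no gene or that overlapped several genes, in each of the 4 libraries; right, the first 2 principal components of log2 CPM over 18612 genes, 1 point per library. Gemini-Cur replicate 1 had 7.93% of reads overlapping several genes, against 19.4% to 21.96% in the other 3 libraries, and lay alone on the first component.

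The 5 protein-coding genes named on the higher side in Gemini-Cur cells, by the smallest unadjusted p under the naming rule, which asks for a mean of at least 5 CPM, were AKR1C2, AKR1C1, AKR1B10, CYP4F11 and PCLO. AKR1C2 (ENSG00000151632, chromosome 10, 4987400 to 5018031) and its neighbour AKR1C1 (ENSG00000187134, chromosome 10, 4963253 to 4983283) encode aldo-keto reductases that reduce steroids and reactive carbonyls. AKR1C2 stood at 15.1 ± 1.23 CPM in untreated and 73.2 ± 5.06 CPM in Gemini-Cur cells (SD, n = 2 per group), and AKR1C1 at 31.8 ± 2.74 and 129 ± 5.60 CPM. Their log2 differences were 2.27 (SE 0.38) and 2.02 (SE 0.39). AKR1B10 (ENSG00000198074, chromosome 7, 134527592 to 134541408), a reductase of aldehydes, measured 20.4 ± 2.46 and 68.5 ± 22.5 CPM. CYP4F11 (ENSG00000171903, chromosome 19, 15912367 to 15934867), a cytochrome P450 that hydroxylates fatty acids, measured 1.47 ± 0.421 CPM in untreated cells, and 24.9 and 7.83 CPM in Gemini-Cur replicates 1 and 2. Where the treated libraries differ by more than 3-fold, as here, their values are given singly, replicate 1 first. PCLO (ENSG00000186472, chromosome 7, 82754013 to 83162930), which encodes a presynaptic scaffold protein, measured 1.89 ± 0.369 and 11.1 ± 4.44 CPM.

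On the lower side, HSPA6 (ENSG00000173110, chromosome 1, 161524540 to 161526910), a strictly stress-inducible HSP70, measured 72.8 ± 23.2 CPM in untreated and 12.3 ± 5.81 CPM in Gemini-Cur cells, a log2 difference of -2.56 (SE 0.52). CDKN1C (ENSG00000129757, chromosome 11, 2883213 to 2885773), the cyclin-dependent kinase inhibitor p57, measured 15.98 ± 0.257 and 5.03 ± 1.25 CPM. WDR76 (ENSG00000092470, chromosome 15, 43826963 to 43868419) measured 25.2 ± 1.35 and 9.89 ± 0.265 CPM. TCN1 (ENSG00000134827, chromosome 11, 59852800 to 59866575), a vitamin B12 binding protein, measured 9.41 ± 1.78 and 2.75 ± 0.859 CPM. SNORD3B-1 (ENSG00000265185, chromosome 17, 19061912 to 19062669), a U3 small nucleolar RNA, measured 83.5 ± 9.42 and 18.8 ± 1.34 CPM. TP53 itself (ENSG00000141510, chromosome 17, 7661779 to 7687550) measured 93.6 ± 0.332 and 62.5 ± 14.8 CPM, a log2 difference of -0.58 (SE 0.40). In each of these 11 genes both treated libraries lay on the same side of both untreated ones, which the naming rule itself asks for in all of them but TP53.

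None of the 18612 genes passed edgeR's quasi-likelihood test, and the smallest Benjamini-Hochberg adjusted p was 0.977, which also holds for the 11 genes above. At an unadjusted p under 0.05 there were 576 genes, 426 of them higher in Gemini-Cur cells. DESeq2 called 37 genes, 34 higher and 3 lower, and limma-voom called 0. Of the 11 genes above, DESeq2 called AKR1C2 (adjusted p = 0.00369), CYP4F11 (0.00235), HSPA6 (0.00948), AKR1C1 (0.0135), SNORD3B-1 (0.0135) and PCLO (0.0380). Both treated libraries lay above both untreated ones in 16.5% of genes and below them in 16.99%, where chance gives 16.7% in each direction. Without Gemini-Cur replicate 1, edgeR called 351 genes, and without Gemini-Cur replicate 2 it called 6678. AKR1C1 and AKR1C2 share sequence with each other and with AKR1C3, as does SNORD3B-1 with other U3 copies, so reads can be left out or divided wrongly among such copies.

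NRF2 target genes, which serve glutathione synthesis, NADPH supply, iron storage and carbonyl detoxification, were higher as a list in Gemini-Cur cells. Of 30 members measured, 19 lay above both untreated libraries in both treated ones and 0 lay below. The median member was 1.72-fold higher than the untreated mean in Gemini-Cur replicate 1 and 1.77-fold higher in replicate 2. In replicate 2 all 30 members were above the untreated mean, and in replicate 1 there were 20. With edgeR no member passed over all genes tested, and 2 passed adjusted over the list alone, AKR1C2 (edgeR adjusted p = 0.0291) and AKR1C1 (0.0307). DESeq2 called these 2 and SLC7A11 (adjusted p = 0.0286) over all genes tested. The list rose by limma camera with a preset correlation (adjusted p = 5.38e-06 over 36 lists), with adjusted p = 0.587 with an estimated correlation. The call was lost without Gemini-Cur replicate 2 and held under 8 of 13 alternatives. The mean shift on the log2 scale was 0.556 without Gemini-Cur replicate 2, 0.852 without replicate 1 and 0.704 with all 4 libraries. A fit without a treated replicate rests on 1 treated library, so it does not show whether the rise would recur.

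**Figure D2:**
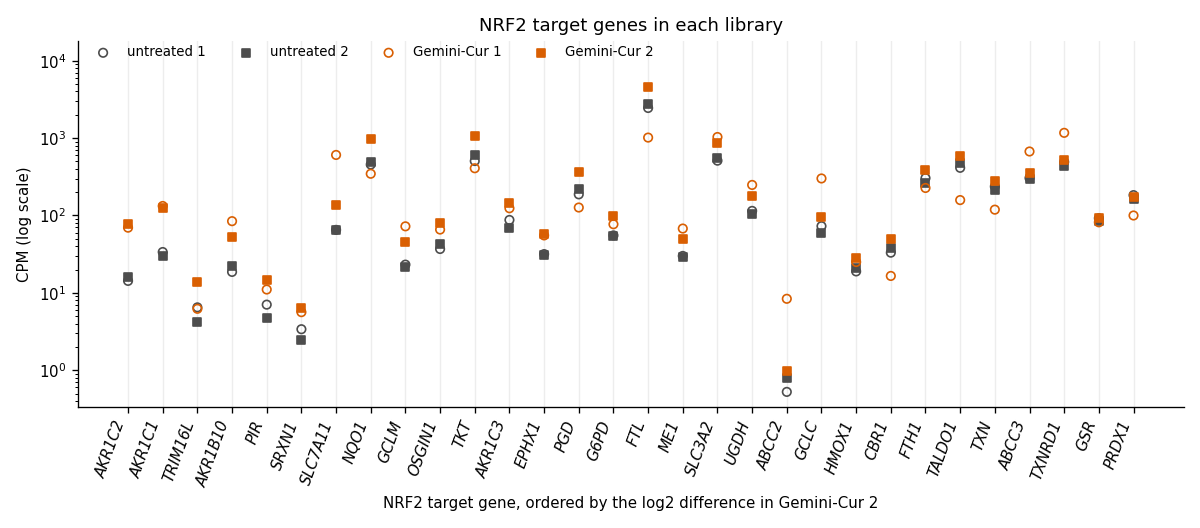
CPM (log axis) of the 30 NRF2 target genes in each library, ordered by the log2 difference of Gemini-Cur replicate 2 from the untreated mean; circles are replicate 1, squares replicate 2, grey untreated and orange Gemini-Cur. All 30 squares of Gemini-Cur replicate 2 lie above the untreated mean, and 20 of the 30 circles of Gemini-Cur replicate 1 do.

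Metallothioneins, small cysteine-rich proteins that bind zinc and copper, were also higher as a list. MT1G measured 0.447 ± 0.0580 CPM in untreated cells, and 9.57 and 2.72 CPM in Gemini-Cur replicates 1 and 2, and passed adjusted over the list alone (edgeR adjusted p = 0.0316), as the only member to do so, and DESeq2 called it over all genes tested (adjusted p = 0.0136). MT2A measured 7.96 ± 1.20 and 18.7 ± 3.08 CPM. Of 8 members, 5 lay above both untreated libraries in both treated ones, and the medians were 2.83-fold and 1.77-fold higher in replicates 1 and 2. The list rose by camera (adjusted p = 6.80e-04, and adjusted p = 0.587 with an estimated correlation), with 0.0598 without Gemini-Cur replicate 2 and a span of 4.16e-04 to 0.743 over 12 alternatives. MT1 genes are near-identical, so reads can be left out or divided wrongly among them. Xenobiotic metabolism and transporter genes did not pass (camera adjusted p = 0.134, medians 0.25 and 0.39 on the log2 scale in replicates 1 and 2), but passed as higher without Gemini-Cur replicate 1 (0.0126, and adjusted p = 0.743 with an estimated correlation). Among their 20 members, the conjugating enzymes UGT1A6 (7.96 ± 0.253 and 23.9 ± 6.61 CPM) and UGT1A1 (1.51 ± 0.0377 CPM, then 12.98 and 3.08 CPM) had the smallest p, and these isoforms share exons. Ferroptosis and iron genes did not pass (adjusted p = 0.999). Their 20 members included the cystine transporter SLC7A11, at 65.1 and 64.4 CPM in untreated cells and 605 and 138 CPM in Gemini-Cur replicates 1 and 2. The iron transporter SLC11A2 measured 245 ± 12.99 and 123 ± 71.8 CPM.

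Genes of protein folding moved in both directions. ER chaperone and ERAD genes, which fold and clear secretory proteins, were higher as a list, with 18 of 24 members above both untreated libraries in both treated ones and 0 below. Their medians were 2.67-fold higher in replicate 1 and 1.26-fold higher in replicate 2. SYVN1, a ubiquitin ligase of ER degradation, measured 25.5 ± 0.490 and 67.8 ± 40.5 CPM, and the disulfide-forming ERO1B 7.71 ± 0.814 CPM, then 53.1 and 10.6 CPM. The list rose by camera (adjusted p = 1.18e-05, and adjusted p = 0.595 with an estimated correlation), and the adjusted p without a replicate spanned 2.62e-06 to 0.00294. HSF1 heat-shock genes were lower as a list, with 11 of 24 members below both untreated libraries and 2 above. Their medians were -0.78 and -0.31 in replicates 1 and 2, against -0.49 and 0.03 for random lists matched on expression and exon length, of which a share of 0.12 was as low in replicate 1 and 2e-04 in replicate 2. The stress-inducible chaperones HSPA1A (111 ± 27.9 and 45.3 ± 0.296 CPM) and HSPA1B (126 ± 30.0 and 54.7 ± 7.86 CPM) had the smallest p, and they are near-identical copies. The heat-shock list fell by camera (adjusted p = 0.0220, and adjusted p = 0.587 with an estimated correlation), and the call was lost without untreated replicate 1 (0.120), untreated replicate 2 (0.190) or Gemini-Cur replicate 2 (0.152), where the mean shift was -0.49, -0.34 and -0.57 on the log2 scale, against -0.42 with all 4 libraries. Genes of ATF4 and the integrated stress response did not pass (adjusted p = 0.512), with SLC7A11 and its partner subunit SLC3A2 (535 ± 33.9 and 954 ± 111 CPM) at the smallest p among 30. The 26S proteasome subunit genes did not pass (adjusted p = 0.260). Their median log2 difference was -0.69 in replicate 1 and 0.24 in replicate 2. The list passed as higher without Gemini-Cur replicate 1 (0.0166, and adjusted p = 0.743 with an estimated correlation) and as lower without replicate 2 (0.00533). With an estimated correlation and all 4 libraries its adjusted p was 0.797. PSMA3 (27.8 ± 8.31 and 43.1 ± 9.50 CPM) and PSMD6 (24.5 ± 0.495 and 31.0 ± 5.06 CPM) had the smallest p of 31. Autophagy and lysosome genes did not pass (adjusted p = 0.881), and NPC1 (23.0 ± 3.37 and 50.5 ± 31.9 CPM) and MAP1LC3B (50.9 ± 6.64 and 84.1 ± 36.4 CPM) had the smallest p of 32.

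**Figure D3:**
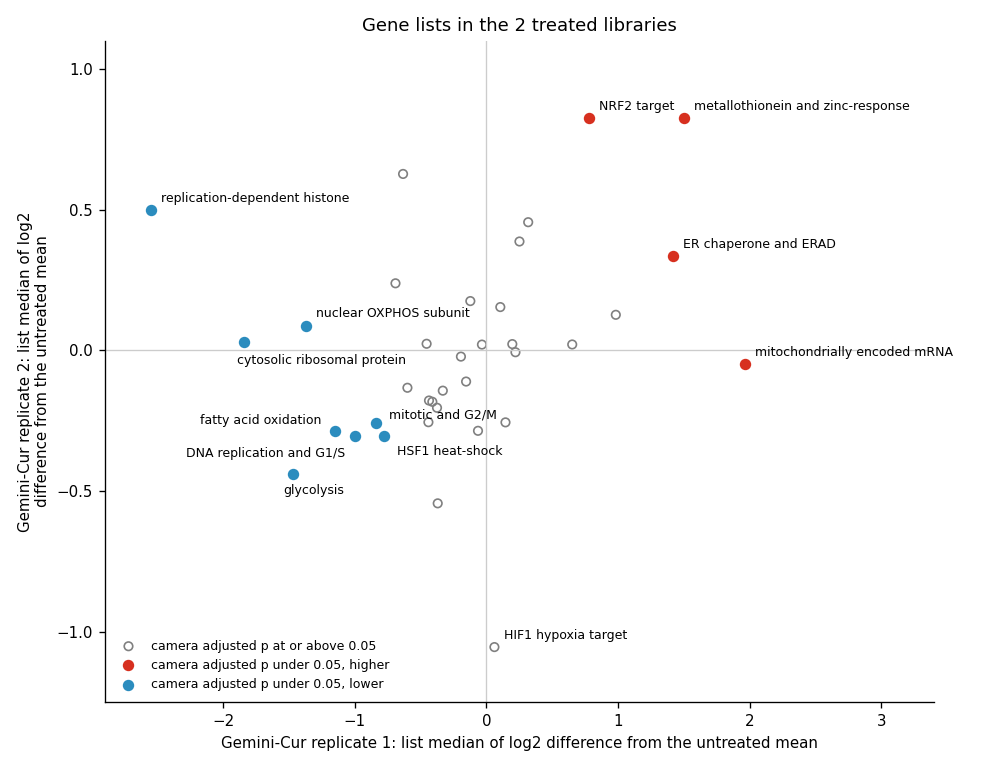
Median log2 difference from the untreated mean over the members of each of 36 gene lists, in Gemini-Cur replicate 1 (horizontal) and replicate 2 (vertical); filled points passed camera with a preset correlation at an adjusted p under 0.05. NRF2 targets lay at 0.78 and 0.82 in the 2 libraries, whereas histone genes lay at -2.55 and 0.50.

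Glycolysis genes, which convert glucose to pyruvate and lactate, were lower as a list, with 13 of 20 members below both untreated libraries in both treated ones and 0 above. The medians were 2.77-fold lower in Gemini-Cur replicate 1 and 1.36-fold lower in replicate 2, and matched random lists had a median of -0.39 on the log2 scale in replicate 1 (list -1.47). PFKFB4, a regulator of phosphofructokinase, measured 69.7 ± 25.8 and 25.8 ± 6.43 CPM, and the enolase ENO2 81.8 ± 14.4 and 42.3 ± 1.77 CPM. The list fell by camera (adjusted p = 1.19e-05, and adjusted p = 0.587 with an estimated correlation), and the adjusted p without a replicate spanned 2.70e-04 to 0.00265. HIF1 hypoxia target genes did not pass (adjusted p = 0.0560). Their median log2 difference was 0.06 in replicate 1 and -1.05 in replicate 2, where 1 of 20 members lay above the untreated mean. CA9, a carbonic anhydrase induced by hypoxia, measured 223 ± 32.3 and 110 ± 13.99 CPM, while the collagen crosslinker LOX measured 0.307 ± 0.106 and 2.64 ± 0.0398 CPM. Without Gemini-Cur replicate 1 the hypoxia list fell (adjusted p = 1.86e-06, and adjusted p = 0.743 with an estimated correlation). It also passed as lower with exon length and GC content trends removed (adjusted p = 0.00753, and 0.602 with an estimated correlation), where its medians were -0.39 in replicate 1 and -0.98 in replicate 2. Over 12 alternatives the adjusted p spanned 1.86e-06 to 0.743.

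Genes of ribosomes and mitochondria differed between the treated libraries. The 49 cytosolic ribosomal protein genes had a median 3.59-fold below the untreated mean in Gemini-Cur replicate 1 and a median log2 difference of 0.03 in replicate 2. RPL4 measured 3026, 3020, 1043 and 2485 CPM in untreated replicates 1 and 2 and Gemini-Cur replicates 1 and 2, and RPS25 measured 586, 579, 214 and 469 CPM. Nuclear OXPHOS subunit genes, which build the respiratory chain, had medians of -1.37 and 0.09 over 34 members. SDHA (56.5 ± 6.81 and 33.5 ± 14.6 CPM) and COX7C (148 ± 32.4 and 88.7 ± 49.1 CPM) had their smallest p. The 13 mitochondrially encoded mRNAs had medians of 1.96 and -0.05, with MT-ND2 (5.66 ± 2.02 CPM, then 23.9 and 7.15 CPM) and MT-ND5 (21.0 ± 1.35 CPM, then 97.99 and 21.4 CPM) at the smallest p. Camera called the ribosomal proteins lower (adjusted p = 1.67e-07), the OXPHOS subunits lower (5.55e-04) and the mitochondrial mRNAs higher (0.00979), each with adjusted p = 0.595 with an estimated correlation. Without Gemini-Cur replicate 1 the adjusted p was 0.656, 0.506 and 0.947, and the mean shift of the ribosomal and OXPHOS lists changed sign. In Gemini-Cur replicate 1, random lists matched on expression and exon length also lay below the untreated mean, with medians of -0.88 for the ribosomal list (-1.84) and -0.71 for the OXPHOS list (-1.37). The mitochondrial mRNA call was also lost without untreated replicate 2 (0.202). Genes of MYC and ribosome biogenesis did not pass (adjusted p = 0.0872), but passed as higher without Gemini-Cur replicate 1 (4.90e-04), under the stricter filter (0.0161) and with trends removed (0.00753). With an estimated correlation the adjusted p was 0.743 without Gemini-Cur replicate 1, 0.594 with trends removed and 0.595 with all 4 libraries. Both treated libraries lay above both untreated ones in 13 of 29 members, among them RRP12 (37.4 ± 7.38 and 70.9 ± 3.01 CPM) and the spermidine synthase SRM (4.996 ± 1.55 and 10.03 ± 0.661 CPM).

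Cell-cycle genes were lower as lists in both treated libraries. Of 37 DNA replication and G1/S genes, 29 lay below both untreated libraries in both treated ones and 0 above, with medians 1.998-fold lower in replicate 1 and 1.23-fold lower in replicate 2. The replication factors GINS1 (38.8 ± 5.81 and 21.0 ± 5.27 CPM) and MCM4 (193 ± 17.7 and 102 ± 20.8 CPM) had the smallest p. Of 36 mitotic and G2/M genes, 19 lay below and 1 above, with medians 1.79-fold and 1.20-fold lower. The mitotic kinase CDK1 measured 93.7 ± 17.1 and 53.4 ± 1.12 CPM, and HMMR, a spindle protein, 15.01 ± 2.04 and 8.32 ± 0.124 CPM. Camera called the replication list (adjusted p = 1.09e-06) and the mitotic list (0.00111) lower, each with adjusted p = 0.587 with an estimated correlation. Without a replicate the adjusted p spanned 2.03e-06 to 0.00117 for replication and 0.00568 to 0.0337 for mitosis. In Gemini-Cur replicate 1, matched random lists had medians of -0.46 for the replication list (-0.999) and -0.45 for the mitotic list (-0.84). Replication-dependent histone genes, whose mRNAs lack poly(A) tails, had a median log2 difference of -2.55 in replicate 1 and 0.50 in replicate 2. H2AC4 measured 78.7, 97.0, 8.32 and 110 CPM in untreated replicates 1 and 2 and Gemini-Cur replicates 1 and 2, and H2BC9 measured 144, 167, 21.4 and 202 CPM. Camera called the histone list lower (adjusted p = 5.55e-04, and adjusted p = 0.595 with an estimated correlation), and without Gemini-Cur replicate 1 it was called higher (1.23e-05, and adjusted p = 0.743 with an estimated correlation). Matched random lists had a median of -1.65 in replicate 1, against -2.52 for the 28 histone genes they were matched to. Histone genes are near-identical copies, so reads can be left out or divided wrongly among them.

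**Figure D4:**
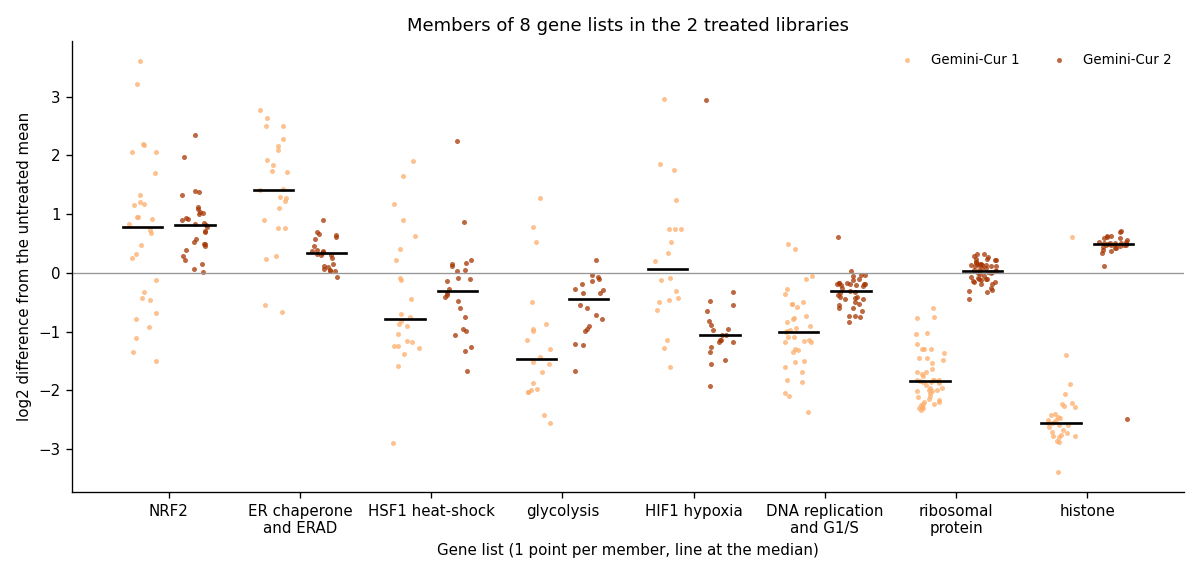
Log2 difference of each member of 8 gene lists from the untreated mean (vertical axis), in Gemini-Cur replicate 1 (light) and replicate 2 (dark), 1 point per gene and a line at the median. NRF2 medians lay at 0.78 and 0.82, ribosomal protein medians at -1.84 and 0.03, and HIF1 medians at 0.06 and -1.05.

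Genes of p53 and cell death did not pass as lists. TP53 target genes had a camera adjusted p of 0.505 and medians of -0.19 and -0.02 over 26 members. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, measured 182 ± 28.4 and 121 ± 43.2 CPM, and GADD45A 41.0 ± 9.07 and 29.1 ± 7.25 CPM. Pro-apoptotic genes had an adjusted p of 0.356, with the BH3-only gene BMF (57.4 ± 3.49 and 30.6 ± 21.5 CPM) and DIABLO (2.84 ± 0.162 and 5.46 ± 3.80 CPM) at the smallest p of 26. Anti-apoptotic genes had an adjusted p of 0.368. Their co-chaperone BAG3 measured 39.0 ± 2.32 and 24.3 ± 5.90 CPM, and the decoy receptor TNFRSF10C had 21, 17, 4 and 0 reads in untreated replicates 1 and 2 and Gemini-Cur replicates 1 and 2. Homologous recombination and Fanconi genes had an adjusted p of 0.558. BRCA2 measured 57.0, 46.5, 185 and 38.4 CPM and XRCC2 15.04, 15.1, 34.5 and 14.7 CPM in untreated replicates 1 and 2 and Gemini-Cur replicates 1 and 2.

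Fatty acid oxidation and ketogenesis genes were lower as a list, with 9 of 19 members below both untreated libraries in both treated ones and 1 above. HMGCS2, the key enzyme of ketone body synthesis, measured 40.2 ± 6.80 and 19.6 ± 12.6 CPM, and HADH 36.4 ± 2.88 and 20.8 ± 7.10 CPM. The list fell by camera (adjusted p = 0.00558, and adjusted p = 0.595 with an estimated correlation). The call was lost without Gemini-Cur replicate 1, where the mean shift was -0.145 on the log2 scale. It was also lost without untreated replicate 2, where the mean shift was -0.527. With all libraries the list's mean shift was -0.627. Its medians were -1.15 in Gemini-Cur replicate 1 and -0.28 in replicate 2. Fatty acid synthesis genes did not pass (adjusted p = 0.0806), but passed as higher under the stricter filter (0.0367) and with trends removed (0.0418, and adjusted p = 0.594 with an estimated correlation), with the NADPH-producing malic enzyme ME1 (29.4 ± 0.914 and 59.0 ± 12.4 CPM) and the elongase ELOVL6 (8.55 ± 1.05 and 15.3 ± 3.67 CPM) at the smallest p of 12. Cholesterol synthesis genes did not pass either (adjusted p = 0.339), with INSIG1 (69.6 ± 3.53 and 40.7 ± 16.7 CPM) and HMGCS1 (23.8 ± 0.659 and 39.3 ± 20.4 CPM) at the smallest p of 24.

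Inflammatory, immune and signalling lists did not pass the camera test with all 4 libraries and no trend removal. Of these, NF-kB genes passed as lower without Gemini-Cur replicate 1 (adjusted p = 0.0222), Wnt targets as lower without untreated replicate 2 (0.0354) and immediate early genes as higher with trends removed (0.0308). With an estimated correlation the adjusted p was 0.743 for NF-kB genes without Gemini-Cur replicate 1, 0.645 for immediate early genes with trends removed, and 0.587 for Wnt targets with all 4 libraries. NF-kB and inflammatory genes had an adjusted p of 0.0560 and medians of -0.44 and -0.26, with 9 of 23 members below both untreated libraries and 2 above. Their cytokines LTB (4.46 ± 1.70 CPM, then 0.339 and 1.54 CPM) and CSF1 (12.9 ± 1.51 and 6.76 ± 2.18 CPM) had the smallest p. Interferon-stimulated genes had an adjusted p of 0.114, with IFI6 (293 ± 2.23 and 160 ± 61.9 CPM) and MX2 (24.1 ± 0.0133 and 16.1 ± 1.93 CPM) at the smallest p of 25. MHC class I presentation genes had an adjusted p of 0.260. The peptidase ERAP1 measured 25.6 ± 4.41 and 51.6 ± 31.6 CPM, and TAP2 measured 20.1, 14.9, 40.3 and 11.99 CPM in untreated replicates 1 and 2 and Gemini-Cur replicates 1 and 2. Immediate early and AP-1 genes had an adjusted p of 0.197. The transcription factors FOSB (9.31, 8.74, 164 and 29.3 CPM in the same order) and EGR1 (14.3, 10.9, 72.3 and 32.8 CPM) had the smallest p of 25, and edgeR's adjusted p over the list alone was 0.0855. DESeq2 called FOSB over all genes tested (adjusted p = 0.00235). Wnt/beta-catenin target genes had an adjusted p of 0.0649, with the protease MMP7 (99.8 ± 12.8 and 55.8 ± 7.04 CPM) and the Wnt inhibitor NKD1 (44.4 ± 0.187 CPM, then 7.495 and 30.9 CPM) at the smallest p of 19.

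Markers of intestinal identity did not pass as lists. Enterocyte and colonocyte markers had a camera adjusted p of 0.148, with CEACAM7 (20.7 ± 1.63 and 11.02 ± 3.23 CPM) and the transcription factor HNF4A (17.8 ± 1.39 and 26.1 ± 1.61 CPM) at the smallest p of 14. Goblet and secretory cell markers had an adjusted p of 0.431. FCGBP measured 2.20, 1.77, 14.5 and 3.30 CPM, and AGR2, a disulfide isomerase of mucus-secreting cells, 129, 104, 1111 and 135 CPM in untreated replicates 1 and 2 and Gemini-Cur replicates 1 and 2. Intestinal stem cell markers had an adjusted p of 0.779, with LRIG1 (11.4 ± 0.147 and 21.6 ± 2.79 CPM) and ALDH1A1 (268 ± 14.1 and 414 ± 151 CPM) at the smallest p of 11. Epithelial junction and keratin genes had an adjusted p of 0.874. KRT19 measured 1290, 1982, 304 and 1029 CPM and CLDN1 12.4, 9.46, 66.7 and 11.4 CPM in the same order. Mesenchymal and EMT genes had an adjusted p of 0.0825 and passed as lower without Gemini-Cur replicate 1 (0.00426, and adjusted p = 0.743 with an estimated correlation), with TNC (27.6 ± 1.05 and 14.9 ± 3.08 CPM) and THBS1 (25.4 ± 3.14 and 51.5 ± 32.3 CPM) at the smallest p of 15. The median, mean and test differed in sign for intestinal stem cell markers (median log2 difference 0.31, mean -0.02, test higher) and for leukocyte markers (-0.05, 0.00, higher). In the autophagy and epithelial lists the mean shift on the log2 CPM scale lay below 0 (-0.01 and -0.04) while the test pointed higher.

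Markers of other cell types formed 3 lists. Of 12 fibroblast markers 2 were measured, too few for a list test. COL1A1 stood at 2.50 ± 0.0146 and 2.12 ± 0.896 CPM, and COL6A3 at 0.0239, 2.58, 0.805 and 0.220 CPM in untreated replicates 1 and 2 and Gemini-Cur replicates 1 and 2. Of 11 endothelial markers 4 were measured, with the receptor TEK at 1.56 ± 0.630 and 0.612 ± 0.243 CPM and the adhesion protein ESAM at 61.8 ± 3.83 and 51.5 ± 18.6 CPM. Leukocyte markers had a camera adjusted p of 0.935 over 8 members. PTPRC, which encodes CD45, had 0 reads in both untreated libraries and 16 and 10 reads in Gemini-Cur replicates 1 and 2, and the integrin ITGAM measured 5.35 ± 0.413 and 1.58 ± 1.03 CPM. With edgeR no member of any list passed over all genes tested, and adjusted over the list alone no member passed outside the NRF2 and metallothionein lists. DESeq2 called 5 list members over all genes tested, AKR1C1, AKR1C2, SLC7A11, MT1G and FOSB.

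In the lncRNA table, the smallest p on the higher side belonged to transcripts that were near 1 CPM or below in untreated cells. ENSG00000259202 (chromosome 15, 67142734 to 67146939) measured 0.130 ± 0.0191 CPM in untreated cells, and 4.98 and 1.32 CPM in Gemini-Cur replicates 1 and 2. SYNE1-AS1 (chromosome 6, 152380546 to 152381564) measured 0.885 ± 0.134 and 6.06 ± 2.90 CPM, ENSG00000231683 (chromosome 6, 53561289 to 53617171) 1.30 ± 0.191 and 8.24 ± 5.0 CPM, and ENSG00000268713 (chromosome 19, 57261354 to 57262738) 0.628 ± 0.362 and 4.85 ± 1.61 CPM. CHRM3-AS2 (chromosome 1, 239703381 to 239730465) measured 0.177 ± 0.0133 CPM, then 7.18 and 0.852 CPM. On the lower side stood LINC01559 (chromosome 12, 13371089 to 13387167; 6.86 ± 1.6 and 1.85 ± 0.0840 CPM) and HILPDA-AS1 (chromosome 7, 128455937 to 128469197; 6.54 ± 1.66 and 2.02 ± 0.336 CPM). FKBP9P1 (3.24 ± 0.637 and 0.423 ± 0.179 CPM), ENSG00000288913 (3.95 ± 1.61 and 0.776 ± 0.281 CPM) and ENSG00000291174 (6.46 ± 2.04 and 1.79 ± 0.314 CPM) were also lower, and the annotation used here gives them no position. Among 33 lncRNAs studied in colon cancer, 16 lay above both untreated libraries in both treated ones and 2 below, with medians of 0.61 and 0.27 in replicates 1 and 2. Over all 5410 lncRNAs 983 lay above and 838 below, with medians of 0.20 and 0.04, and the difference of the list from the rest was not tested. The 4 with the smallest p were MALAT1 (7.47 ± 0.510 CPM, then 47.8 and 12.2 CPM), MIR22HG (8.48 ± 0.363 CPM, then 46.6 and 13.7 CPM), NEAT1 and LUCAT1 (6.22 ± 1.70 CPM, then 78.7 and 8.19 CPM). NEAT1, the scaffold of nuclear paraspeckles, measured 76.0, 65.3, 1336 and 92.0 CPM in untreated replicates 1 and 2 and Gemini-Cur replicates 1 and 2.

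None of the 5410 lncRNAs passed edgeR's test (smallest adjusted p = 0.998, shared by the 10 named transcripts), with 217 at an unadjusted p under 0.05, of which 173 were higher. DESeq2 called 20 and limma-voom 0. Without Gemini-Cur replicate 2 edgeR called 666, without Gemini-Cur replicate 1 it called 1, and none passed within the colon cancer list adjusted over the list alone (smallest adjusted p = 0.268). Every lncRNA identifier also stood in the gene table, where the same identifiers held 6.78%, 6.88%, 29.3% and 8.56% as many reads as in the lncRNA table for untreated replicates 1 and 2 and Gemini-Cur replicates 1 and 2. The gene table leaves out reads that overlap several genes, and 2495 of the 5410 lncRNAs had under 50% of their lncRNA-table reads there (median 64.2%). The 2 most abundant lncRNAs of each library held 65.6%, 62.5%, 24.01% and 57.2% of the lncRNA-table reads, in the same order of libraries, and so weigh on the pooled shares. Among the named ones, SYNE1-AS1 kept 4.14%, ENSG00000268713 0.425%, ENSG00000288913 35.9% and HILPDA-AS1 0% of their reads. With the strand setting not given, such reads cannot be told from reads of an overlapping gene on either strand.

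Without Gemini-Cur replicate 1, the remaining treated library was compared with both untreated ones, on the assumption that it varies as they do. Every call below rests on that 1 treated library, and genes of a list can vary together. The enrichment p-values therefore do not measure whether a change would recur in another treated culture. In that comparison edgeR called 142 genes higher and 209 lower. NRF2 targets made up 18 of the genes called higher, of 30 measured (Fisher's exact test, adjusted p = 1.53e-29). Examples, chosen after their values were seen, were the quinone reductase NQO1 (455 and 496 CPM in untreated replicates 1 and 2, 971 in Gemini-Cur replicate 2), the pentose phosphate enzyme TKT (505, 599 and 1056 CPM) and GCLM of glutathione synthesis (23.2, 21.5 and 45.1 CPM). In Gemini-Cur replicate 1, NQO1 and TKT measured 346 and 408 CPM and GCLM 72.4 CPM. HIF1 targets made up 12 of the genes called lower, of 20 measured (adjusted p = 1.29e-17), and 1 of those called higher. Also among the genes called lower were 8 of 20 glycolysis genes (adjusted p = 6.29e-10) and 7 of 24 HSF1 heat-shock genes (1.14e-07). NDRG1, a hypoxia-induced gene, measured 1691 and 2168 CPM in untreated cells, 503 CPM in Gemini-Cur replicate 2 and 1385 CPM in replicate 1. Lactate dehydrogenase LDHA measured 1511 and 1392, then 617 and 797 CPM in the same order. Smaller enrichments were 4 ER chaperone genes (adjusted p = 4.66e-04), 4 genes of MYC and ribosome biogenesis (8.28e-04), 4 of ATF4 (8.28e-04) and 2 metallothioneins (0.0109) among the genes called higher. Among the genes called lower were 4 NF-kB (0.00110), 3 Wnt (0.01) and 3 ferroptosis genes (0.0105). Some of these lists also had members called in the other direction, with 2 MYC genes and 1 ATF4 gene lower (adjusted p = 0.187 and 0.729) and 2 ferroptosis genes higher (0.0587). Lists share members, so these counts are not independent: NRF2 targets include SLC7A11 and SLC3A2 of the 4 ATF4 genes and both ferroptosis genes called higher. With the estimated correlation no list passed camera without Gemini-Cur replicate 1. So few residual degrees of freedom are left there that this cannot tell changed from unchanged lists.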

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

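The test of exon length and GC content trends was chosen after related results had been seen; the tests of genomic DNA and unspliced RNA were set before. In Gemini-Cur replicate 1, 28.2% of uniquely aligned reads were assigned to no gene, above the 6.58% and 5.63% of the untreated libraries, while Gemini-Cur replicate 2 had 6.49%. These reads take no part in the comparisons. Reads overlapping several genes made up 7.93% in Gemini-Cur replicate 1, against 19.4% and 21.96% in untreated replicates 1 and 2 and 20.9% in Gemini-Cur replicate 2.

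The same library stood apart across genes, with an SD of log2 differences from the untreated mean of 1.47, against 0.975 for Gemini-Cur replicate 2. Genomic DNA as the whole source of the extra unassigned reads is argued against by 381 olfactory receptor genes, which held 0.655 reads per kb of exon (95% Poisson interval 0.603 to 0.710), where an even spread of those reads over the genome would give 5.38; a smaller amount stays open, since these genes held 589 reads there and 99, 37 and 94 in untreated replicates 1 and 2 and Gemini-Cur replicate 2. With trends of exon length, GC content and genomic span removed, the SD was 1.33, against 0.972, which argues against such trends as the whole cause. More unspliced or nuclear RNA cannot be told apart from other causes. The partial rank correlation across 17713 genes with genomic span over exon length, at like exon length, was 0.0505 (95% interval 0.0358 to 0.0652). It lay under the bound of 0.1 set beforehand to argue against this explanation. Yet it lay above the -0.0656 of Gemini-Cur replicate 2 and the -0.0440 between the untreated libraries. The nuclear RNAs NEAT1 (1336 against 76.0 and 65.3 CPM in untreated cells), MALAT1 (47.8 against 7.83 and 7.11) and KCNQ1OT1 (222 against 52.6 and 42.3) were higher there. RNA that is not nuclear was also counted higher there: all 13 mitochondrially encoded mRNAs lay above the untreated mean, with a median log2 difference of 1.96. For these mRNAs the untreated libraries themselves differed by a median of -0.61, replicate 2 minus 1. Reads overlapping several genes, a smaller share in this library, are left out of gene counts. Their part in the mitochondrial rise was not tested. With that limit, the rise of NEAT1, MALAT1 and KCNQ1OT1 does not single out nuclear RNA. The explanation is left open, a reading chosen after the correlation was seen, because that bound rested on no known amount of unspliced RNA. Intron reads, if only exons were counted, would also be among the unassigned reads. No biological explanation was tested, since both treated libraries have the same label, and a difference in library preparation or culture stays open and untested. The strand setting is not given, so a difference in how reads were counted stays open and untested too.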

How the results depend on the processing

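The trend removal, its combination and that of leaving out Gemini-Cur replicate 1 with an estimated correlation, the gene-table counts of lncRNAs and the NRF2 list without AKR1C genes were chosen after seeing the data. The count of genes called was 0 under DESeq2's size factors, the stricter filter, limma-voom, the 1.5-fold threshold, thinning, without mitochondrial genes and with trends removed. It was 114 with no filter and 37 with DESeq2, and 0 to 6678 without a replicate: 0 without either untreated library, 351 without Gemini-Cur replicate 1 and 6678 without replicate 2. For lncRNAs it was 80 with no filter, 20 with DESeq2, 0 to 666 without a replicate, and 0 under the other alternatives without a block. With the replicate number as a block edgeR called 20 genes and 21 lncRNAs, and 19 and 18 with thinning as well; deviations of same-numbered libraries correlated at 0.13, a single value since 2 libraries per group mirror each other, and no label says what a number marks, so whether the numbers pair the cultures stays open. The block ended the heat-shock call (camera adjusted p = 0.0586) and no other list call, while the mean shift of the heat-shock list stayed at -0.418. Camera with an estimated correlation has few residual degrees of freedom, so a call lost there does not show that a list was unchanged. The 12 list calls became 0 with an estimated correlation, alone, without Gemini-Cur replicate 1 or with trends removed, and 0 with fry, which asks another question. They numbered 12, 14, 11 and 16 with DESeq2's size factors, the stricter filter, the block and trends removed, and 10 to 14 without a replicate; 7 remained, in the same direction, among the 14 without Gemini-Cur replicate 1. DESeq2's size factors moved the median log2 difference of all genes from 0.0351 to 0.0767, and no filter moved it to 0.206. Apart from the fewer libraries or genes they use, the cause of these shifts was not tested. Matched random lists, also chosen afterwards, were drawn for 12 lists. Their medians lay below 0 in Gemini-Cur replicate 1 for each of the 12, from -1.65 (histones) to -0.13 (HIF1). In the direction of the list test, a share under 0.05 of random lists was as extreme in replicate 1 for all of the 12 but HSF1 (0.12) and HIF1 (0.72), and in replicate 2 for all but ribosomal proteins (0.36), OXPHOS (0.73) and histones, which lay above the random lists there (1e-04 as high).

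Mean shifts of 16 lists, in log2 CPM, changed sign somewhere. Without a replicate they spanned -0.427 to 0.0355 for TP53 targets, -0.631 to 0.0587 for pro-apoptotic genes, -2.53 to 0.426 for histones, -0.0828 to 0.211 for ATF4, -0.742 to 0.191 for the proteasome, -0.112 to 0.0845 for autophagy, -0.824 to 0.106 for HIF1, -1.32 to 0.0586 for OXPHOS, -1.88 to 0.0496 for ribosomal proteins, -0.0052 to 0.386 for MYC, -0.247 to 0.116 for stem cell markers, -0.114 to 0.0347 for epithelial genes, -0.0128 to 0.513 for xenobiotic genes, -0.249 to 0.0610 for ferroptosis and -0.292 to 0.192 for leukocyte markers. Without Gemini-Cur replicate 1 epithelial genes stood at 0.0244. The stricter filter gave 0.0899 for autophagy, 0.0378 for stem cell markers, 0.0175 for goblet markers, 0.0622 for epithelial genes and 0.116 for ferroptosis. Trend removal gave 0.114 for autophagy, 0.0548 for epithelial genes and 0.0800 for leukocyte markers. Of 94 named genes, 85 kept their sign throughout. The other 9 spanned, without a replicate, -0.55 to 1.22 (TAP2), -0.66 to 0.0657 (ESAM), -2.55 to 4.27 (COL6A3), -0.73 to 0.14 (COL1A1), -0.43 to 1.86 (BRCA2), -0.0381 to 1.22 (XRCC2), -0.0309 to 1.55 (DIABLO), -3.37 to 0.33 (H2AC4) and -2.84 to 0.37 (H2BC9); COL6A3 was 0.60 with limma-voom and 0.20 with the replicate block. The cause was not tested. With the spread of all 4 libraries, 0% of simulated 2-fold and 68% of 16-fold changes were recovered, against 56% and 80% with the spread of the untreated libraries alone. No simulated library stood apart, so these shares need not hold for the data. Thinning to the smallest library left both counts of calls at 0.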

Other observations

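The tests of explanations in this part, and the genes named next, were chosen after their results, or closely related ones, had been seen. Without Gemini-Cur replicate 1, edgeR also called genes outside the lists. The collagen lysyl hydroxylase PLOD2 measured 232 and 222 CPM in untreated replicates 1 and 2, 91.7 CPM in Gemini-Cur replicate 2 and 289 CPM in Gemini-Cur replicate 1 (adjusted p = 2.03e-07). GPNMB, a membrane glycoprotein, measured 5.75, 4.07, 0.302 and 4.95 CPM in the same order. In the gene table the lncRNA LINC00659 measured 30.1, 31.3, 79.3 and 33.4 CPM. In the lncRNA table no lncRNA was called higher in that comparison. With all 4 libraries none of these 3 genes passed. Whether the treated libraries differ from each other at these genes was not tested.

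NRF2 target genes were higher in both Gemini-Cur libraries, which may be a response to the treatment, as a hypothesis found and tested on the same data. With exon length, GC content and genomic span trends removed, the smaller of the list medians of the treated libraries was 0.81 on the log2 scale, which argues against these trends as the whole cause. Without AKR1C1, AKR1C2 and AKR1C3, which left 27 members, the smaller median was 0.736, so the list median did not rest on these paralogs. Leaving out so few members can move a median only little. Whether shared reads raised the counts of the paralogs themselves was not tested. Of 10000 random lists matched on expression and exon length to 29 members, a share of 1e-04, the smallest they can give, had a median as high in either treated library. Random genes were drawn independently, so this share does not cover members that vary together. A difference between cultures unrelated to the treatment stays open and untested. The list's camera call was lost with an estimated correlation (adjusted p = 0.587), where few residual degrees of freedom are left. It was also lost without Gemini-Cur replicate 2, where the mean shift was 0.556 on the log2 scale, against 0.704 with all libraries.

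HIF1 target genes were lower in Gemini-Cur replicate 2 than in replicate 1, with medians of -1.05 and 0.06 on the log2 scale. With trends removed the medians were -0.978 and -0.386 and the list passed camera as lower (adjusted p = 0.00753, and 0.602 with an estimated correlation), so that replicate 1 being level with the untreated cells depends on that correction. The median over 20 members of replicate 2 minus replicate 1 was then -0.701 (95% bootstrap interval over members -1.15 to -0.285), against -0.970 before. This argues against trends as the whole cause of the difference between these 2 libraries. The interval takes members as independent and holds no spread between cultures, so it does not show whether the difference would recur. A share of 1e-04 of 10000 matched random lists, the smallest they can give, had a median as low in replicate 2. Random genes were drawn independently, so that share does not cover members that vary together. A difference in oxygen or cell density between cultures cannot be told apart from the treatment, with 1 library on each side; the untreated libraries differed by 0.129, which is 1 pair only.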
